A study of Pseudomonas putida KT2440 with 12 samples.

How the data were processed

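RNA of Pseudomonas putida KT2440 from 12 batch cultures was measured by strand-specific sequencing (100 bp single-end reads, a stranded TruSeq mRNA kit, 2 sequencing rounds). Cells grew on citrate, ferulate, glucose or serine at 30 °C and 250 rpm in 100 mL of medium, and 20 mL were harvested. Cultures were started at an OD600 of 0.1 on glucose and citrate and of 0.01 on ferulate and serine. Reads were aligned with Bowtie2 per the submitters' processing notes. The counting program, the genome build, the version of Bowtie2 and whether the sequencing rounds were summed are not given in the sources used here.

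Each deposited table held 5556 features of 1 library with a raw and a normalized column. The raw column was taken to hold the authors' estimated counts, that is expected counts per feature truncated to whole numbers, and was used as deposited. This was judged from the normalized column, a score made by the authors and not used for any test. Divided by 1 factor per library, it lay 0 to 1 above the whole count, with a tolerance of 0.05, for 100% of the features of fewer than 300 counts in each library. The features were 5350 genes, 22 rRNA, 74 tRNA, 72 predicted RNAs and 38 antisense features, 28 of them antisense to rRNA and 10 to other genes. Of all features, 110 named no gene, and these held 3.94% to 12.2% of the counts of a library. A symbol was given for 1411 genes, and genes without one are called by their locus tag and product. None of the locus tags matched the separate table of gene symbols (0 matched), so symbols are those of the deposited tables.

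The analysis used the 5350 genes, with rRNA, tRNA, predicted and antisense features left out of library sizes and tests because rRNA held 83.1% to 93.1% of the counts. The counts on genes were 1570055, 1448613 and 2081626 in the citrate libraries, 1432393, 1217274 and 886151 in the ferulate libraries, 1987410, 570393 and 577327 in the glucose libraries, and 1065806, 2252789 and 835842 in the serine libraries. Levels are given in CPM, counts scaled to a common library size. Between 66 and 398 genes had 0 counts in a library, the most in glucose libraries 2 and 3 (365 and 398). No library looked like a copy of another.

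Genes were filtered with filterByExpr, scaled by TMM factors and tested with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, with robust dispersion estimates and all 12 samples in 1 fit (8 residual degrees of freedom, common dispersion 0.0206). This left 4624 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Errors of log2 fold changes are standard errors, and levels are mean CPM with the standard deviation of 3 cultures. Folds of single genes are those of the fitted model, unless given as a bound or with an interval. They can differ from the ratio of the mean CPM beside them. All 6 pairs of sources were compared. Genes called in the same direction against each of the other 3 sources were counted as higher or lower in that source. Where a group had 0 counts, folds were taken against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact Poisson interval at 95% confidence.

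The 29 lists of genes, the comparisons, the thresholds, the rule for naming genes and most alternatives were set before the data were examined. The lists were glucose uptake and periplasmic oxidation, the Entner-Doudoroff pathway, gluconeogenesis, tricarboxylate and dicarboxylate uptake, the tricarboxylic acid cycle, the glyoxylate shunt and methylcitrate cycle, ferulate to protocatechuate, the protocatechuate branch, the benzoate and catechol branch, phenylacetate and homogentisate, one-carbon and formaldehyde oxidation, serine and glycine use, serine and cysteine synthesis, amino acid synthesis, multidrug efflux, ribosomal proteins, ATP synthase and NADH dehydrogenase, terminal oxidases, flagella and chemotaxis, chaperones and heat shock, oxidative stress, pyoverdine and iron uptake, nitrogen assimilation, sulfur assimilation, phosphate starvation, polyhydroxyalkanoate metabolism, branched-chain amino acid degradation, phage-related genes, and transposases and mobile elements. PP_0253 and PP_0489 were listed but were not among the features used here. PP_1616, PP_2184, PP_3970 and PP_2905 were dropped from their lists because the tables annotate them with another product. The phosphate starvation list was drawn by symbols starting with pst, pho or phn, and so includes phoP and phoQ by name alone. Lists were tested against glucose with camera of limma 3.58.1, with the correlation between genes estimated from log2 CPM (prior count 2), adjusted over the 29 lists and 3 comparisons. Members that rose, fell or were not called are counted among the tested members only, as the filter on low counts removed part of some lists. In the benzoate and catechol branch 3 of 12 members were tested, and in phenylacetate and homogentisate pathways 9 of 21.

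Named genes followed this rule. For each comparison with glucose, they were the 10 highest and the 10 lowest log2 fold changes among called genes whose 3 values in each group did not overlap and whose mean reached 10 CPM. The 2 largest rises and the 2 largest falls of each list were added, as were a fixed set of genes and, per source, the 5 genes with the largest smallest fold change over the other sources. This made 254 genes, of which a part is named in the text.

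The procedure was tested on simulated data in which 200 of the genes were changed. Of genes changed by 1.5 on the log2 scale, 90%, 87% and 84% were recovered at the depths of citrate, ferulate and serine against glucose, and of genes changed by 3, 99%, 98% and 97%, with 4, 5 and 2 calls among unchanged genes. A list raised as a whole, the tricarboxylic acid cycle, had an adjusted p of 6.2e-05 by camera and 0 other lists were called. The simulated genes varied independently, whereas the estimated correlation of that list in the real data was 0.47. This test therefore does not show how often camera finds a changed list whose genes vary together.

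The alternatives were RLE and upper quartile factors, DESeq2 1.42.0, no filter on low counts, only the 6 samples of the compared groups, a block for the replicate number, rRNA and tRNA kept, adjusted p alone, an adjusted p of 0.01, each replicate left out in turn, a correlation preset at 0.01 and fry in place of camera. A mean of at least 30 CPM, counts rounded to the nearest whole number instead of truncated, glucose library 1 as the only glucose library and predicted RNAs kept were chosen after seeing the data, as was leaving out single libraries for the runs of neighbouring genes, the order of leading genes, the lower bounds and 1 predicted RNA. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.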

Results

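Pseudomonas putida KT2440, a soil bacterium with a broad diet of organic acids, sugars, amino acids and aromatic compounds, was grown in batch culture on 1 of 4 sole carbon sources, and its RNA was sequenced. The sources were glucose, a sugar, citrate, a tricarboxylic acid, ferulate, an aromatic acid of plant cell walls, and serine, an amino acid. There were 3 biological replicate cultures per condition and 12 samples in all. Citrate, ferulate and serine were supplied at 10 mM and glucose at 0.5% (w/v). Cultures were harvested at an OD600 of 0.6 on glucose, 0.4 on citrate, 0.3 to 0.4 on ferulate and 0.15 to 0.2 on serine.

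Each library was a count table over 5556 annotated features, of which 5350 were genes other than rRNA and tRNA. The citrate libraries 1, 2 and 3 held 50358551, 50490651 and 64126244 counts in total. The ferulate libraries held 42951498, 40252103 and 36672798 counts, the glucose libraries 63430673, 18501055 and 19444188 counts, and the serine libraries 23286140, 57072119 and 34298531 counts. Between 83.1% and 93.1% of these counts lay on rRNA. The counts left on genes ranged from 570393 in glucose library 2 to 2252789 in serine library 2, and glucose library 3 held 577327. Glucose libraries 2 and 3 also carried 8.75 and 4.05 antisense rRNA counts per 100 rRNA counts, whereas glucose library 1 carried 0.223 and the 9 libraries of the other sources carried 0.0936 to 0.908.

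**Figure D1:**
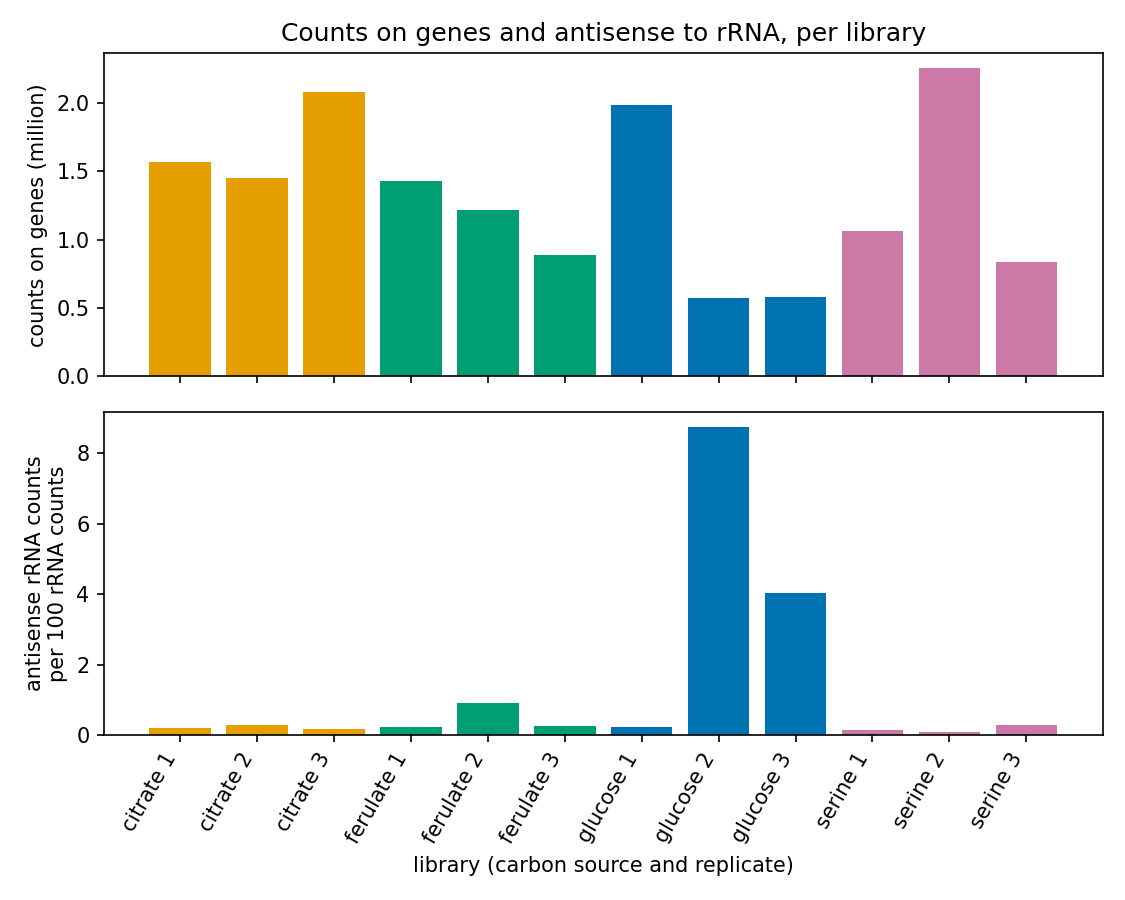
Bars in the upper panel give the counts on genes (M) and bars in the lower panel the antisense rRNA counts per 100 rRNA counts, 1 bar per library, coloured by carbon source. Glucose libraries 2 and 3 have the fewest gene counts, 570393 and 577327, and the most antisense rRNA counts, 8.75 and 4.05 per 100 rRNA counts.

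Libraries of the same source were alike. Pearson's r across genes (log2 CPM, with genes that are not independent replicates) was 0.975 to 0.986 between citrate libraries, 0.975 to 0.979 between ferulate libraries, 0.959 to 0.961 between glucose libraries and 0.977 to 0.983 between serine libraries. Between sources it was 0.787 to 0.901. The first 3 principal components held 44.6%, 25% and 15.9% of the variance. Glucose and serine lay at opposite ends of the first component, and ferulate lay apart from the other sources on the second.

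**Figure D2:**
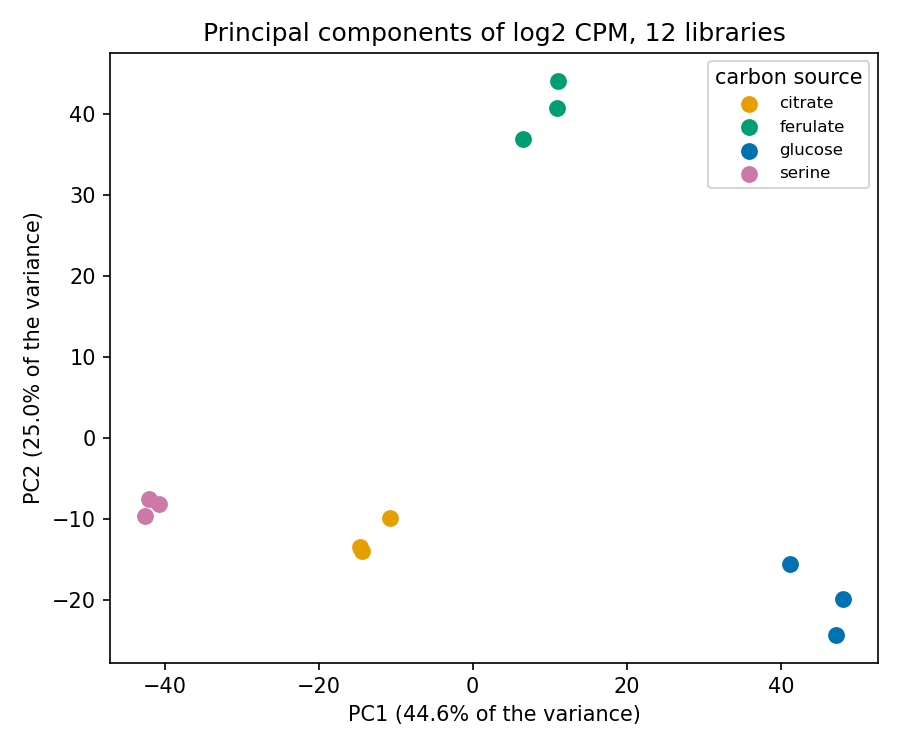
Each point is 1 of the 12 libraries, placed by the first (44.6% of the variance) and second (25%) principal component of log2 CPM and coloured by carbon source. The 3 libraries of each source lie together, with glucose at 41.22 to 48.03 and serine at -42.50 to -40.72 on the first component.

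The first comparison asked which transcripts differ when citrate replaces glucose as the only carbon source. PP_0147, a citrate transporter (positions 156417 to 157724, minus strand), stood at 977 ± 176 CPM in citrate and 29 ± 6.14 CPM in glucose (SD, n = 3), with a fitted rise of 34.3-fold. PP_1419, a porin (positions 1618941 to 1620230, minus strand) beside the TctC gene PP_1418 and the TctB gene PP_1417 of a tricarboxylate transporter, stood at 450 ± 40.2 CPM in citrate and 4.79 ± 3 CPM in glucose (SD, n = 3). At the other end was PP_1016, an ABC transporter permease beside a sugar-binding protein gene (positions 1159286 to 1160194, plus strand), with 1 count over the 3 citrate libraries and 1221 over the 3 glucose libraries. This was a ratio of 2514 per unit of library size, with an exact 95% Poisson interval of 450 to 99378 that covers counting error only, as do all such intervals and lower bounds below. Without citrate library 3, which held that count, PP_1016 was at least 529-fold lower in citrate. Positions are those given in the annotation of the count tables, whose genome build is not stated in the sources used here.

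Of 4624 genes tested, 1047 were called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05 and a change of at least 1 on the log2 scale), 686 higher and 361 lower in citrate. Values given below for single genes without a unit are log2 fold changes with their standard error. PP_1953, a short chain dehydrogenase (positions 2209753 to 2210562, plus strand), had a log2 fold change of 6.82 ± 0.30 (adjusted p = 8.3e-14) and stood at 484 ± 56.4 CPM in citrate and 3.68 ± 1.54 CPM in glucose. The lactate genes lctP, an L-lactate transporter, and lldD, L-lactate dehydrogenase, rose by log2 fold changes of 5.45 ± 0.34 (adjusted p = 1.5e-09) and 4.31 ± 0.37 (adjusted p = 5.8e-08). PP_1418 (TctC) rose by 4.79 ± 0.28 (adjusted p = 9.2e-12). PP_1417 (TctB) held 224 counts in citrate and 2 in glucose, a ratio of 54.4 with a 95% interval of 14.9 to 452 (fitted log2 fold change 5.57). The ratio was 20.9 (5.73 to 174) without glucose library 1, 87.8 (15.6 to 3482) without library 2 and 87.9 (15.6 to 3489) without library 3, and the gene was at least 22-fold higher with glucose library 1 as the only glucose library, where it had 0 counts. PP_2773, a hypothetical protein, held 146 and 3 counts, a ratio of 23.6 with an interval of 7.93 to 116 (fitted 4.48). All 3 glucose counts lay in glucose library 1, with a ratio of 14.5 (4.88 to 71.3) against that library alone and at least 9.17-fold without it. PP_5167, a hypothetical protein, and PP_2177, a transcriptional regulator, rose by 4.64 ± 0.24 and 4.53 ± 0.46 on the log2 scale. The fitted log2 fold changes of the genes that fell most were -8.56 ± 0.32 for PP_1017, -7.86 ± 0.21 for PP_1018 and -6.98 ± 0.23 for PP_1015, all in 1 stretch with PP_1016, and -6.61 ± 0.32 for kguK, a kinase of the 2-ketogluconate route. PP_3781 and PP_3783, from a stretch of genes with a non-ribosomal peptide synthetase, had -6.47 ± 0.60 and -6.00 ± 0.52.

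Among the lists of carbon metabolism, 2 rose, 16 fell and 4 were not called of the 22 genes of glucose uptake and periplasmic oxidation (median log2 fold change -5.20, adjusted p = 0.0213 with an estimated correlation). The outer membrane porin gene oprB-1 and the gluconate transporter gene gntP had log2 fold changes of -5.51 ± 0.18 and -5.93 ± 0.20, whereas gcd, the periplasmic glucose dehydrogenase, and its neighbour oprB-2, a second porin gene, rose by 1.36 ± 0.18 and 1.38 ± 0.25. In the Entner-Doudoroff list of 11 genes, the route by which this bacterium breaks down glucose, 2 rose, 6 fell and 3 were not called (median log2 fold change -1.98, adjusted p = 0.275 with an estimated correlation). Here zwf-1, pgl, edd and eda had log2 fold changes of -3.11 ± 0.18, -3.58 ± 0.19, -2.39 ± 0.24 and -3.55 ± 0.14. In tricarboxylate and dicarboxylate uptake, 7 rose, 2 fell and 4 were not called of 13 (median log2 fold change 1.98, adjusted p = 0.195 with an estimated correlation). PP_5131, a dicarboxylate symporter, stood at -2.10 ± 0.22. In the tricarboxylic acid cycle, 6 rose, 0 fell and 15 were not called of 21 (median log2 fold change 0.37, adjusted p = 0.718 with an estimated correlation), including icd, isocitrate dehydrogenase, at 2.85 ± 0.18, and mqo-3, a malate:quinone oxidoreductase, at 2.62 ± 0.21. The citrate synthase gene gltA, at -0.23 ± 0.16, was not called. In the glyoxylate shunt and methylcitrate cycle, 2 rose, 0 fell and 5 were not called of 7 (median log2 fold change 0.48, adjusted p = 0.634 with an estimated correlation). The called ones were prpD at 1.91 ± 0.27 and aceA, isocitrate lyase, at 1.45 ± 0.16. In gluconeogenesis and the phosphoenolpyruvate-pyruvate-oxaloacetate node, 0 rose, 2 fell and 14 were not called of 16 (median log2 fold change -0.36, adjusted p = 0.514 with an estimated correlation). The called ones were the pyruvate carboxylase subunit genes accC-2 and oadA at -1.91 ± 0.22 and -1.84 ± 0.24.

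In ferulate to protocatechuate, 0 rose, 0 fell and 8 were not called of 8 (median log2 fold change -0.14, adjusted p = 0.853 with an estimated correlation), and fcs, at -0.95 ± 0.31 with an adjusted p of 0.0143, missed the fold threshold. In the protocatechuate branch of the beta-ketoadipate pathway, 4 rose, 1 fell and 6 were not called of 11 (median log2 fold change 0.71, adjusted p = 0.326 with an estimated correlation). The gene pcaD stood at 1.57 ± 0.28. In the benzoate and catechol branch, only 3 of 12 members were tested, of which 0 rose, 1 fell and 2 were not called (median log2 fold change 0.15, adjusted p = 0.969 with an estimated correlation). The mean of -0.22 and the test pointed down while the median was above 0. For phenylacetate and homogentisate pathways, 9 of 21 members were tested, of which 2 rose, 0 fell and 7 were not called (median log2 fold change 0.20, adjusted p = 0.604 with an estimated correlation). PP_4619, maleylacetoacetate isomerase, stood at 1.51 ± 0.43. In serine and glycine use, 5 rose, 0 fell and 11 were not called of 16 (median log2 fold change 0.29, adjusted p = 0.567 with an estimated correlation), among them sda-2, a serine dehydratase, at 1.24 ± 0.20, and gcvH and gcvP-2 of the glycine cleavage system at 1.27 ± 0.21 and 1.54 ± 0.18. For serine and cysteine synthesis, 0 rose, 0 fell and 6 were not called of 6 (median log2 fold change -0.61, adjusted p = 0.391 with an estimated correlation), and in one-carbon and formaldehyde oxidation, 2 rose, 0 fell and 11 were not called of 13 (median log2 fold change 0.58, adjusted p = 0.465 with an estimated correlation). PP_0490, a formate dehydrogenase subunit, stood at 1.37 ± 0.27. Of 67 genes of amino acid synthesis, 0 rose, 15 fell and 52 were not called (median log2 fold change -0.65, adjusted p = 0.168 with an estimated correlation), led by the tryptophan synthase genes trpB and trpA at -3.68 ± 0.21 and -3.35 ± 0.18. In branched-chain amino acid degradation, 2 rose, 0 fell and 5 were not called of 7 (median log2 fold change 0.55, adjusted p = 0.465 with an estimated correlation), namely mmsA-2 at 2.14 ± 0.27 and mmsB at 1.31 ± 0.15.

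Of the cell's larger machines, 0 rose, 19 fell and 35 were not called of the 54 ribosomal protein genes (median log2 fold change -0.92, adjusted p = 0.169 with an estimated correlation), and rpmH and rpsT had log2 fold changes of -2.18 ± 0.19 and -1.96 ± 0.22. The levels of these genes summed to 8.4% ± 1.13 of the scaled library size in citrate and 17.5% ± 0.886 in glucose (SD, n = 3). These percents are not shares of the gene counts. In ATP synthase and NADH dehydrogenase, 0 rose, 0 fell and 21 were not called of 21 (median log2 fold change -0.27, adjusted p = 0.422 with an estimated correlation). In the terminal oxidases, 11 rose, 0 fell and 7 were not called of 18 (median log2 fold change 1.76, adjusted p = 0.275 with an estimated correlation). PP_0104 and PP_0106, cytochrome c oxidase subunits I and III, rose by 2.80 ± 0.28 and 2.94 ± 0.32. With glucose library 1 as the only glucose library these became 3.44 and 3.95, and without it the latter was 2.18. Of 85 genes of flagella and chemotaxis, 6 rose, 0 fell and 79 were not called (median log2 fold change 0.21, adjusted p = 0.747 with an estimated correlation), including the flagellin gene fliC at 1.26 ± 0.20. In multidrug efflux, 7 rose, 0 fell and 23 were not called of 30 (median log2 fold change 0.36, adjusted p = 0.208 with an estimated correlation). PP_0715, an efflux outer membrane lipoprotein, stood at 1.80 ± 0.33.

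In chaperones and heat shock, 0 rose, 4 fell and 13 were not called of 17 (median log2 fold change -0.62, adjusted p = 0.275 with an estimated correlation). The protease genes hslV and hslU stood at -1.77 ± 0.16 and -1.31 ± 0.16. For oxidative stress, 1 rose, 0 fell and 10 were not called of 11 (median log2 fold change -0.16, adjusted p = 0.966 with an estimated correlation). The 1 called was PP_3668, a catalase/peroxidase, at 2.75 ± 0.23, and the mean was 0.19 while the median and the test pointed down. In pyoverdine and iron uptake, 1 rose, 2 fell and 27 were not called of 30 (median log2 fold change -0.12, adjusted p = 0.87 with an estimated correlation). The receptor gene for iron dicitrate, fecA, stood at 2.69 ± 0.57 (1.97 without glucose library 1, and a ratio of 12.5 with an interval of 3.37 to 105 against glucose library 1 alone, with 2 counts), and tonB and exbB, of the energy supply for such receptors, stood at -1.32 ± 0.29 and -1.30 ± 0.22. In nitrogen assimilation, 0 rose, 4 fell and 8 were not called of 12 (median log2 fold change -0.49, adjusted p = 0.174 with an estimated correlation). The gene gltB of glutamate synthase stood at -1.72 ± 0.14. In sulfur assimilation, 7 rose, 1 fell and 21 were not called of 29 (median log2 fold change 0.02, adjusted p = 0.778 with an estimated correlation). The gene ssuE and PP_3528, both of aliphatic sulfonate use, stood at 3.45 ± 0.25 and 3.22 ± 0.35 and cysNC at -1.25 ± 0.14. In phosphate starvation, 0 rose, 2 fell and 8 were not called of 10 (median log2 fold change -0.40, adjusted p = 0.174 with an estimated correlation). In polyhydroxyalkanoate metabolism, the making and breaking of carbon storage granules, 6 rose, 0 fell and 1 were not called of 7 (median log2 fold change 1.22, adjusted p = 0.169 with an estimated correlation). The gene phaG stood at 3.30 ± 0.21 and the granule protein gene PP_5008 at 2.97 ± 0.17. In phage-related genes, 4 rose, 2 fell and 26 were not called of 32 (median log2 fold change 0.40, adjusted p = 0.747 with an estimated correlation), and in transposases and mobile elements, 8 rose, 1 fell and 54 were not called of 63 (median log2 fold change 0.13, adjusted p = 0.96 with an estimated correlation).

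Adjusted over the list alone, all 29 lists gave the same numbers of members higher and lower in citrate. By camera, 1 of the 29 lists passed, glucose uptake and periplasmic oxidation, and the other 28 had adjusted p values of 0.168 to 0.969. With an adjusted p alone and no fold threshold, 2200 genes differed, 1101 of them higher.

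Ferulate was compared with glucose to show which transcripts differ when an aromatic acid is the only carbon source. Every gene tested in the lists ferulate to protocatechuate and protocatechuate branch, which cover the path from ferulate to the tricarboxylic acid cycle, rose. The first step, feruloyl-CoA synthase, is encoded by fcs (positions 3794567 to 3796336, minus strand), which stood at 2725 ± 177 CPM in ferulate and 12.3 ± 4.44 CPM in glucose (SD, n = 3). Its fitted rise was 196-fold. The vanillate demethylase gene vanA (positions 4263705 to 4264772, plus strand) stood at 1001 ± 71 CPM in ferulate and 3.26 ± 1.1 CPM in glucose (SD, n = 3), with a fitted rise of 282-fold. As on citrate, PP_1016 fell. It went from 484 ± 99.2 CPM in glucose to 3.01 ± 2.92 CPM in ferulate (SD, n = 3), a log2 fold change of -7.51 ± 0.34 (-6.79 without ferulate library 1, -8.25 without ferulate library 3).

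Of 4624 genes tested, 632 were called, 455 higher and 177 lower in ferulate. Of the 8 genes of the list ferulate to protocatechuate, 8 rose, 0 fell and 0 were not called (median log2 fold change 7.65, adjusted p = 0.0213 with an estimated correlation). Besides fcs and vanA, with log2 fold changes of 7.61 ± 0.22 (adjusted p = 3.0e-17) and 8.14 ± 0.23 (adjusted p = 3.0e-17), these included vanB at 7.14 ± 0.23, vdh, vanillin dehydrogenase, at 7.68 ± 0.22 and ech, the hydratase/lyase, at 7.88 ± 0.30 (7.23 without glucose library 1, 8.88 with it as the only glucose library). Of the 11 genes of the protocatechuate branch of the beta-ketoadipate pathway, which opens the aromatic ring and leads to the tricarboxylic acid cycle, 11 rose, 0 fell and 0 were not called (median log2 fold change 4.37, adjusted p = 0.0057 with an estimated correlation). Here pcaF stood at 7.88 ± 0.25 (adjusted p = 1.6e-16), pcaI and pcaJ of the CoA-transferase at 6.05 ± 0.20 and 6.51 ± 0.25, the ring-opening dioxygenase genes pcaG and pcaH at 4.16 ± 0.24 and 4.37 ± 0.28, pcaB at 4.22 ± 0.22 and the transporter gene pcaK at 5.38 ± 0.18. Outside these lists, PP_3740, of the major facilitator family, stood at 8.03 ± 0.22 (adjusted p = 3.0e-17), PP_3349, annotated as a 3-hydroxyphenylpropionic transporter, at 8.04 ± 0.26 (adjusted p = 1.8e-16), and its neighbour PP_3350, a hypothetical protein, at 8.45 ± 0.29 (adjusted p = 2.7e-16), which was 9.23 without glucose library 1.

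The stretch from PP_2675 to PP_2681 held genes with very few counts in glucose. PP_2678, with a beta-lactamase domain, and PP_2681, annotated as PqqD of pyrroloquinoline quinone synthesis, had 0 counts in all 3 glucose libraries, so their folds are lower bounds against a floor of 3 counts over the glucose group. They were at least 138-fold and at least 84.2-fold higher in ferulate, or at least 53.2-fold and at least 32.4-fold without glucose library 1, the deepest. The 0 counts are of the truncated values. With counts rounded to the nearest, the fitted log2 fold changes went from 10.74 to 8.38 for PP_2678 and from 10.01 to 7.64 for PP_2681. PP_2675, a cytochrome c-type protein of the same stretch, had 3 counts over the glucose libraries and 1555 over the ferulate libraries, a ratio of 379 with an exact 95% Poisson interval of 129 to 1840. Its level varied between the ferulate cultures, at 461 ± 226 CPM (SD, n = 3), and so did that of PP_2676, at 485 ± 243 CPM. In one-carbon and formaldehyde oxidation, which handles the methyl group taken from vanillate, 2 rose, 0 fell and 11 were not called of 13 (median log2 fold change 0.47, adjusted p = 0.195 with an estimated correlation). PP_1617, S-formylglutathione hydrolase, and PP_0257, a formate dehydrogenase accessory protein, were the called ones, at 3.81 ± 0.18 (adjusted p = 1.7e-13) and 3.95 ± 0.30 (adjusted p = 7.9e-10) (4.62 without glucose library 1), and fdhA, formaldehyde dehydrogenase, at 0.70 ± 0.21, was not called. In the benzoate and catechol branch, 1 rose, 1 fell and 1 were not called of 3 (median log2 fold change 0.79, adjusted p = 0.567 with an estimated correlation). The regulator gene benR stood at 1.23 ± 0.24. For phenylacetate and homogentisate pathways, 1 rose, 0 fell and 8 were not called of 9 (median log2 fold change 0.21, adjusted p = 0.548 with an estimated correlation).

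In glucose uptake and periplasmic oxidation, 2 rose, 14 fell and 6 were not called of 22 (median log2 fold change -5.09, adjusted p = 0.0213 with an estimated correlation). The gluconate kinase gene gnuK stood at -8.25 ± 0.28 (adjusted p = 3.1e-16), PP_1017 at -8.22 ± 0.34, PP_3384, gluconate 2-dehydrogenase, at -6.36 ± 0.33 and the cofactor gene pqqC at 1.29 ± 0.19. In the Entner-Doudoroff list, 0 rose, 6 fell and 5 were not called of 11 (median log2 fold change -3.27, adjusted p = 0.143 with an estimated correlation). The gene zwf-1 stood at -6.34 ± 0.23 and pgl at -6.12 ± 0.23. In gluconeogenesis and the phosphoenolpyruvate-pyruvate-oxaloacetate node, 0 rose, 5 fell and 11 were not called of 16 (median log2 fold change -0.65, adjusted p = 0.169 with an estimated correlation). The gene accC-2 stood at -4.08 ± 0.24 and oadA at -3.42 ± 0.26. In tricarboxylate and dicarboxylate uptake, 6 rose, 0 fell and 7 were not called of 13 (median log2 fold change 0.79, adjusted p = 0.195 with an estimated correlation). The symporter gene PP_1400 stood at 3.98 ± 0.28 and the porin gene PP_1419 at 3.22 ± 0.30. In the tricarboxylic acid cycle, 2 rose, 7 fell and 12 were not called of 21 (median log2 fold change -0.46, adjusted p = 0.388 with an estimated correlation). The gene mqo-2 stood at -1.83 ± 0.16 and sucA at -1.56 ± 0.19. In the glyoxylate shunt and methylcitrate cycle, 1 rose, 0 fell and 6 were not called of 7 (median log2 fold change 0.52, adjusted p = 0.747 with an estimated correlation), and aceA stood at 895 ± 176 CPM in ferulate and 89.3 ± 6.55 CPM in glucose (SD, n = 3), a log2 fold change of 3.33 ± 0.16 (adjusted p = 3.0e-13). In branched-chain amino acid degradation, 0 rose, 0 fell and 7 were not called of 7 (median log2 fold change 0.34, adjusted p = 0.568 with an estimated correlation).

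In serine and glycine use, 0 rose, 4 fell and 12 were not called of 16 (median log2 fold change -0.27, adjusted p = 0.208 with an estimated correlation). The gene gcvH stood at -5.14 ± 0.39, gcvP-1 at -2.48 ± 0.22 and sda-2 at -2.01 ± 0.25. In serine and cysteine synthesis, 0 rose, 2 fell and 4 were not called of 6 (median log2 fold change -0.48, adjusted p = 0.195 with an estimated correlation). The called ones were serA at -1.23 ± 0.16 and serC at -1.34 ± 0.20. Of 67 genes of amino acid synthesis, 2 rose, 10 fell and 55 were not called (median log2 fold change -0.57, adjusted p = 0.143 with an estimated correlation). The gene trpB stood at -2.48 ± 0.20. The members that rose, aroE (PP_2406) at 3.37 ± 0.48 and aroQ-2 at 3.07 ± 0.71, are named for steps of the shikimate pathway. Of 54 ribosomal protein genes, 0 rose, 20 fell and 34 were not called (median log2 fold change -0.78, adjusted p = 0.169 with an estimated correlation). The gene rplD stood at -1.64 ± 0.18, and the list summed to 11.5% ± 0.738 of the scaled library size in ferulate (SD, n = 3). In ATP synthase and NADH dehydrogenase, 0 rose, 4 fell and 17 were not called of 21 (median log2 fold change -0.86, adjusted p = 0.168 with an estimated correlation). The gene nuoCD stood at -1.43 ± 0.18. In the terminal oxidases, 8 rose, 0 fell and 10 were not called of 18 (median log2 fold change 0.81, adjusted p = 0.31 with an estimated correlation). In multidrug efflux, 10 rose, 1 fell and 19 were not called of 30 (median log2 fold change 0.67, adjusted p = 0.143 with an estimated correlation). The RND transporter gene PP_0179 stood at 2.89 ± 0.23 and oprN at 1.68 ± 0.23.

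In flagella and chemotaxis, 8 rose, 0 fell and 77 were not called of 85 (median log2 fold change 0.32, adjusted p = 0.378 with an estimated correlation). PP_2643, a chemotaxis receptor, stood at 4.72 ± 0.21 (adjusted p = 5.6e-14). In chaperones and heat shock, 0 rose, 6 fell and 11 were not called of 17 (median log2 fold change -0.47, adjusted p = 0.174 with an estimated correlation). The gene grpE stood at -1.23 ± 0.16. Nothing was called in oxidative stress, where 0 rose, 0 fell and 11 were not called of 11 (median log2 fold change -0.05, adjusted p = 0.7 with an estimated correlation), or in pyoverdine and iron uptake, where 0 rose, 0 fell and 30 were not called of 30 (median log2 fold change 0.09, adjusted p = 0.714 with an estimated correlation). In nitrogen assimilation, 0 rose, 4 fell and 8 were not called of 12 (median log2 fold change -0.65, adjusted p = 0.143 with an estimated correlation). The glutamine synthetase gene glnA stood at -1.51 ± 0.17. In sulfur assimilation, 2 rose, 0 fell and 27 were not called of 29 (median log2 fold change 0.11, adjusted p = 0.88 with an estimated correlation). The test pointed down while the median and the mean of 0.07 were above 0. For phosphate starvation, 0 rose, 1 fell and 9 were not called of 10 (median log2 fold change -0.22, adjusted p = 0.23 with an estimated correlation). Its members phoP and phoQ, included by symbol alone, stood at 34.7 to 54.4 and 36.1 to 46.4 CPM in ferulate. In glucose they stood at 93.7 to 163 and 94.5 to 104 CPM. In polyhydroxyalkanoate metabolism, 1 rose, 0 fell and 6 were not called of 7 (median log2 fold change 0.63, adjusted p = 0.369 with an estimated correlation). The 1 called was PP_5008 at 1.31 ± 0.18. In phage-related genes, 11 rose, 1 fell and 20 were not called of 32 (median log2 fold change 0.15, adjusted p = 0.544 with an estimated correlation). PP_1562, a terminase subunit, stood at 3.51 ± 0.67 (adjusted p = 0.00132) (2.78 without ferulate library 3, and 172 against 2 counts without glucose library 1, a ratio of 24.2 with an interval of 6.6 to 202). The summed level of the list varied between cultures, at 0.243% ± 0.108 of the scaled library size (SD, n = 3). In transposases and mobile elements, 2 rose, 0 fell and 61 were not called of 63 (median log2 fold change 0.09, adjusted p = 0.916 with an estimated correlation).

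Adjusted over the list alone, 27 of the 29 lists gave the same numbers of members higher and lower, and the calls in sulfur assimilation and in phosphate starvation went to 0. By camera, 3 of the 29 lists passed, and the other 26 had adjusted p values of 0.143 to 0.916. Of the 3, glucose uptake and periplasmic oxidation was not called without ferulate library 1, and ferulate to protocatechuate was not called without glucose library 1. With an adjusted p alone and no fold threshold, 1471 genes differed, 763 of them higher.

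The comparison of serine with glucose asked which transcripts differ when an amino acid is the only carbon source. The gene for an iron-sulfur L-serine dehydratase, sda-3 (positions 3560243 to 3561619, plus strand), which turns serine into pyruvate and ammonia, stood at 3845 ± 48.7 CPM in serine and 42.9 ± 6.82 CPM in glucose (SD, n = 3), an 89.6-fold rise. PP_0106, cytochrome c oxidase subunit III (positions 112162 to 113049, plus strand), stood at 292 ± 16.5 CPM in serine and 8.38 ± 5.42 CPM in glucose, and rpsT, for a ribosomal protein (positions 707068 to 707346, minus strand), at 3326 ± 528 CPM in serine and 25357 ± 2148 CPM in glucose (SD, n = 3).

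Of 4624 genes tested, 1633 were called, 930 higher and 703 lower in serine. The log2 fold change of sda-3 was 6.49 ± 0.21 (adjusted p = 6.3e-16). PP_4034, allantoate amidohydrolase, and PP_4035, a nucleoside transporter, which lie next to each other, rose by 5.41 ± 0.38 (adjusted p = 3.0e-08) and 5.30 ± 0.24 (adjusted p = 1.9e-13), and the former was 4.78 without glucose library 1 and 6.22 without glucose library 3. PP_1640, a hypothetical protein, PP_0711, an isochorismatase family hydrolase, and PP_3629, annotated as a 3-demethylubiquinone-9 3-methyltransferase, rose by 5.54 ± 0.30, 5.30 ± 0.23 and 5.13 ± 0.29. PP_2260, an ATP-binding protein of a sugar ABC transporter, rose by 5.10 ± 0.39 (adjusted p = 3.4e-10). Among the genes that fell were PP_1016 at -7.89 ± 0.34 (adjusted p = 1.5e-13), PP_1017 at -7.64 ± 0.31 (a ratio of 358 with an interval of 122 to 1738 without serine library 2, where serine held 3 counts) and PP_1249, a hypothetical protein, at -6.89 ± 0.50 (adjusted p = 1.0e-07). PP_1249 stood at 142 ± 28.2 CPM in serine and 16843 ± 5095 CPM in glucose (SD, n = 3).

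In serine and glycine use, 3 rose, 5 fell and 8 were not called of 16 (median log2 fold change -0.17, adjusted p = 0.71 with an estimated correlation). Besides sda-3, gcvP-2 rose by 1.60 ± 0.18, whereas gcvH and gcvT-1, of the other set of glycine cleavage genes, had log2 fold changes of -3.84 ± 0.31 and -1.84 ± 0.19. In serine and cysteine synthesis, 0 rose, 2 fell and 4 were not called of 6 (median log2 fold change -0.73, adjusted p = 0.349 with an estimated correlation). The gene serA, the first enzyme of serine synthesis, stood at -2.28 ± 0.17 (adjusted p = 2.0e-10). In one-carbon and formaldehyde oxidation, 6 rose, 2 fell and 5 were not called of 13 (median log2 fold change 0.77, adjusted p = 0.275 with an estimated correlation). PP_0490, a formate dehydrogenase subunit, stood at 2.31 ± 0.25 and fdhA at 1.36 ± 0.20. Of 67 genes of amino acid synthesis, 0 rose, 32 fell and 35 were not called (median log2 fold change -0.99, adjusted p = 0.143 with an estimated correlation). The genes trpB and trpA stood at -4.73 ± 0.23 and -3.74 ± 0.19. In branched-chain amino acid degradation, 5 rose, 1 fell and 1 were not called of 7 (median log2 fold change 1.20, adjusted p = 0.526 with an estimated correlation). The gene mmsA-2 stood at 1.58 ± 0.28 and lpdV at 1.54 ± 0.20. In nitrogen assimilation, 1 rose, 6 fell and 5 were not called of 12 (median log2 fold change -0.69, adjusted p = 0.195 with an estimated correlation). The gene glnA stood at -2.66 ± 0.18.

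In glucose uptake and periplasmic oxidation, 1 rose, 17 fell and 4 were not called of 22 (median log2 fold change -4.85, adjusted p = 0.0339 with an estimated correlation). The member that rose was oprB-2 at 2.62 ± 0.24. In the Entner-Doudoroff list, 1 rose, 6 fell and 4 were not called of 11 (median log2 fold change -2.10, adjusted p = 0.343 with an estimated correlation). The gene eda stood at -4.72 ± 0.15 and gap-1 at -4.43 ± 0.27. In gluconeogenesis and the phosphoenolpyruvate-pyruvate-oxaloacetate node, 0 rose, 9 fell and 7 were not called of 16 (median log2 fold change -1.30, adjusted p = 0.195 with an estimated correlation). The malic enzyme gene maeB stood at -2.02 ± 0.15 and aceF of pyruvate dehydrogenase at -2.12 ± 0.17. In the tricarboxylic acid cycle, 6 rose, 13 fell and 2 were not called of 21 (median log2 fold change -1.36, adjusted p = 0.544 with an estimated correlation). The genes mdh and mqo-3, both for malate oxidation, rose by 2.88 ± 0.27 and 2.73 ± 0.21, whereas gltA, sdhA, sucC and kgdB had -1.39 ± 0.16, -1.36 ± 0.16, -2.29 ± 0.18 and -2.28 ± 0.20. In the glyoxylate shunt and methylcitrate cycle, 2 rose, 3 fell and 2 were not called of 7 (median log2 fold change -0.56, adjusted p = 0.856 with an estimated correlation). The gene prpD stood at 2.34 ± 0.27 and glcB, malate synthase, at -1.32 ± 0.15. In tricarboxylate and dicarboxylate uptake, 1 rose, 1 fell and 11 were not called of 13 (median log2 fold change 0.12, adjusted p = 0.843 with an estimated correlation). The test pointed down while the median and the mean of 0.02 were above 0.

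In ferulate to protocatechuate, 1 rose, 0 fell and 7 were not called of 8 (median log2 fold change 0.21, adjusted p = 0.826 with an estimated correlation). The called one, PP_3354, an acyl-CoA dehydrogenase at 1.34 ± 0.41, was not called without glucose library 1 (0.71). In the protocatechuate branch of the beta-ketoadipate pathway, 2 rose, 0 fell and 9 were not called of 11 (median log2 fold change 0.47, adjusted p = 0.514 with an estimated correlation). The transporter gene pcaT stood at 1.34 ± 0.18. In the benzoate and catechol branch, 1 rose, 0 fell and 2 were not called of 3 (median log2 fold change -0.22, adjusted p = 0.583 with an estimated correlation). The mean of 0.69 and the test pointed up while the median was below 0, with benR at 2.81 ± 0.22. For phenylacetate and homogentisate pathways, 0 rose, 1 fell and 8 were not called of 9 (median log2 fold change 0.23, adjusted p = 0.712 with an estimated correlation). In polyhydroxyalkanoate metabolism, 5 rose, 0 fell and 2 were not called of 7 (median log2 fold change 1.11, adjusted p = 0.275 with an estimated correlation). The granule protein gene PP_5007 stood at 2.86 ± 0.17.

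Of 54 ribosomal protein genes, 0 rose, 43 fell and 11 were not called (median log2 fold change -1.76, adjusted p = 0.169 with an estimated correlation). The gene rpsT stood at -2.93 ± 0.22 (adjusted p = 3.0e-10) and rpmE at -2.74 ± 0.21 (adjusted p = 4.4e-10). The list summed to 6.64% ± 0.683 of the scaled library size in serine against 17.5% ± 0.886 in glucose (SD, n = 3). These percents are not shares of the gene counts. In the terminal oxidases, 11 rose, 5 fell and 2 were not called of 18 (median log2 fold change 1.73, adjusted p = 0.544 with an estimated correlation). The members went both ways. PP_0106 and PP_0105, of the cytochrome c oxidase, rose by 5.50 ± 0.28 (adjusted p = 4.9e-13) and 5.37 ± 0.30 (adjusted p = 2.3e-12), the former at 4.70 without glucose library 1 and 6.47 with it alone, while cyoA, cyoB and cyoD of the ubiquinol oxidase had log2 fold changes of -2.67 ± 0.16, -3.07 ± 0.18 and -3.05 ± 0.20. In ATP synthase and NADH dehydrogenase, 0 rose, 9 fell and 12 were not called of 21 (median log2 fold change -0.94, adjusted p = 0.195 with an estimated correlation). The gene atpA stood at -1.95 ± 0.16. Of 85 genes of flagella and chemotaxis, 42 rose, 2 fell and 41 were not called (median log2 fold change 1.07, adjusted p = 0.169 with an estimated correlation). The flagellin gene fliC stood at 9927 ± 307 CPM in serine and 3140 ± 671 CPM in glucose (SD, n = 3), and flgB and PP_4888, a chemotaxis receptor, rose by 2.91 ± 0.20 (adjusted p = 1.3e-10) and 4.16 ± 0.22 (adjusted p = 1.2e-12). The list summed to 4.02% ± 0.324 of the scaled library size in serine and 1.61% ± 0.1 in glucose (SD, n = 3). In multidrug efflux, 6 rose, 9 fell and 15 were not called of 30 (median log2 fold change -0.29, adjusted p = 0.544 with an estimated correlation). The efflux pump genes ttgA and ttgB stood at -2.18 ± 0.17 and -2.34 ± 0.16 and PP_0715 at 2.69 ± 0.31.

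In chaperones and heat shock, 1 rose, 7 fell and 9 were not called of 17 (median log2 fold change -0.75, adjusted p = 0.275 with an estimated correlation). The gene hslU stood at -2.50 ± 0.17 and groEL at -2.45 ± 0.18. In oxidative stress, 1 rose, 4 fell and 6 were not called of 11 (median log2 fold change -0.46, adjusted p = 0.567 with an estimated correlation). PP_3668, the catalase/peroxidase, stood at 2.25 ± 0.23 and sodB, superoxide dismutase, at -1.54 ± 0.17. In pyoverdine and iron uptake, 4 rose, 2 fell and 24 were not called of 30 (median log2 fold change -0.05, adjusted p = 0.957 with an estimated correlation). The mean of 0.11 and the test pointed up while the median was below 0. In sulfur assimilation, 2 rose, 2 fell and 25 were not called of 29 (median log2 fold change -0.24, adjusted p = 0.662 with an estimated correlation). The gene cysNC stood at -1.70 ± 0.15 and PP_0718, a sulfate transporter, at 1.87 ± 0.23. For phosphate starvation, 0 rose, 0 fell and 10 were not called of 10 (median log2 fold change -0.58, adjusted p = 0.227 with an estimated correlation). In phage-related genes, 7 rose, 2 fell and 23 were not called of 32 (median log2 fold change 0.28, adjusted p = 0.729 with an estimated correlation), and in transposases and mobile elements, 9 rose, 0 fell and 54 were not called of 63 (median log2 fold change 0.29, adjusted p = 0.826 with an estimated correlation).

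Adjusted over the list alone, 28 of the 29 lists gave the same numbers of members higher and lower, and the call in phenylacetate and homogentisate pathways went to 0. By camera, 1 of the 29 lists passed, glucose uptake and periplasmic oxidation, and the other 28 had adjusted p values of 0.143 to 0.957. That list was not called without glucose library 1 or when genes with a mean under 30 CPM were left out, 0 lists passing in either case. With an adjusted p alone and no fold threshold, 2684 genes differed, 1349 of them higher.

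**Figure D3:**
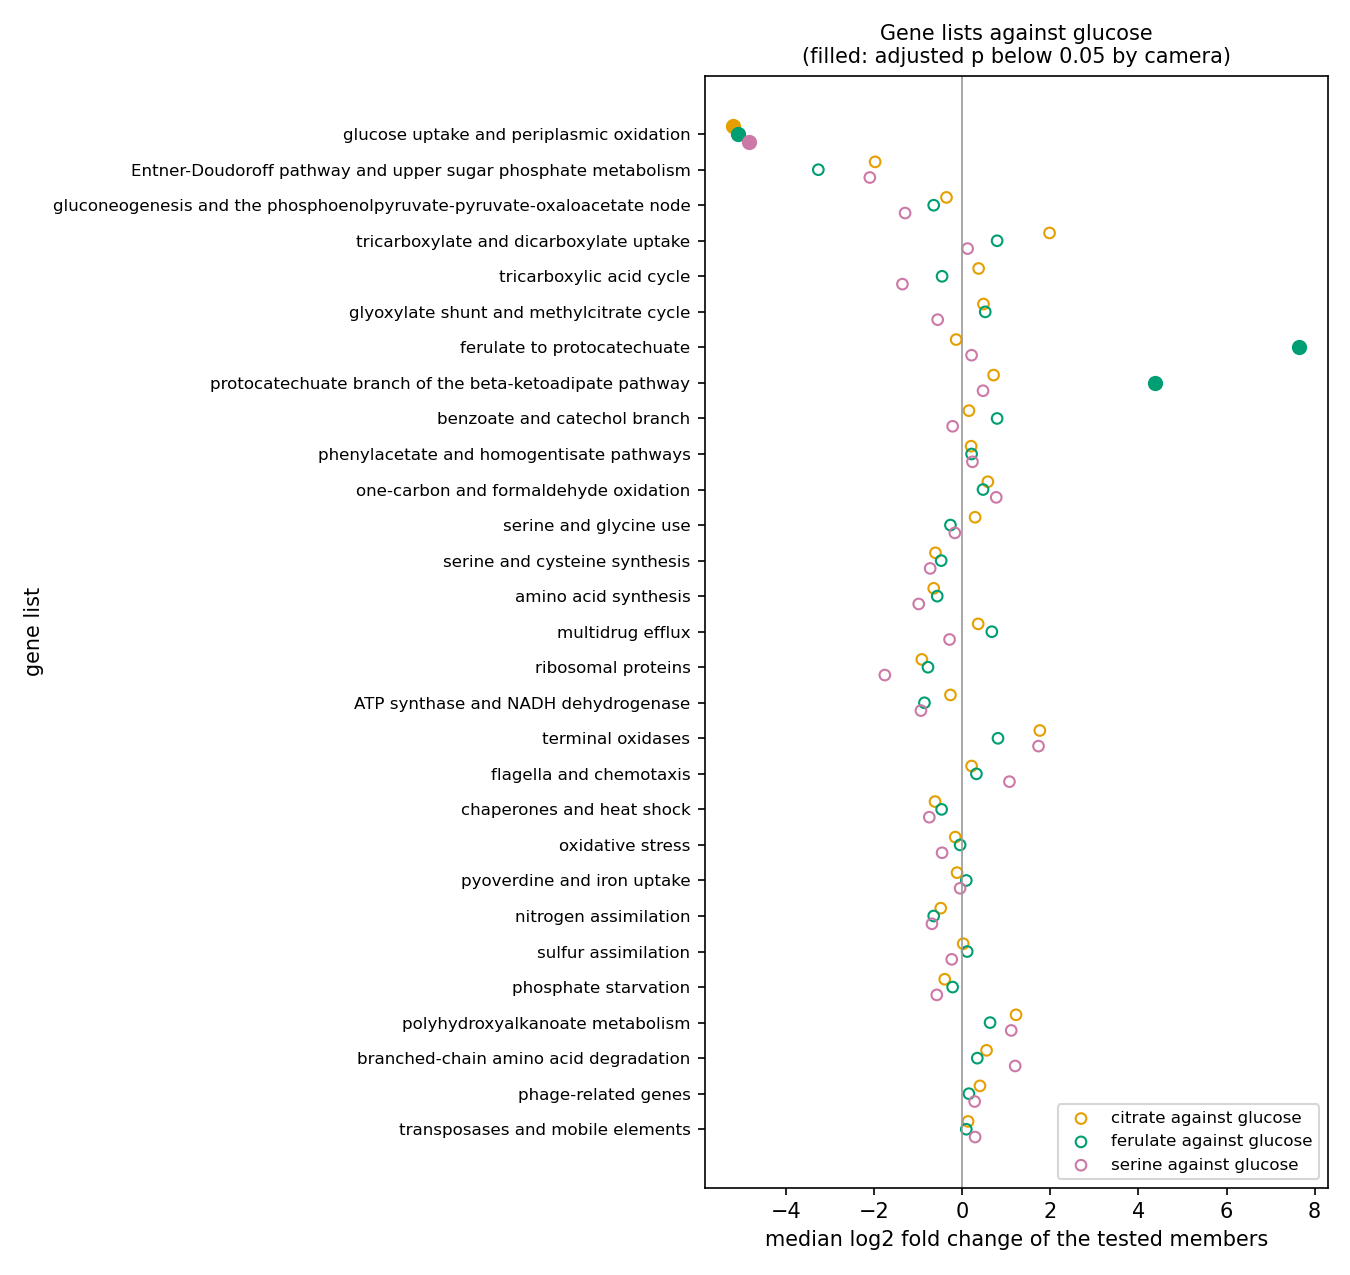
Each circle is the median log2 fold change of the tested members of 1 of the 29 lists against glucose, with citrate, ferulate and serine in different colours and filled circles for lists with an adjusted p below 0.05 by camera. The 3 filled circles on the left are glucose uptake and periplasmic oxidation, at -5.20, -5.09 and -4.85, and those on the right are ferulate to protocatechuate at 7.65 and the protocatechuate branch at 4.37, both in ferulate.

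The sources other than glucose were then compared with each other, to see which differences were not only differences from glucose. Starting density, harvest density and the concentration supplied were stated once per source. Where they differed, no comparison, with or without glucose, can tell them from the carbon source. Ferulate against citrate gave 783 called genes, 371 higher and 412 lower in ferulate. All 8 genes of the list ferulate to protocatechuate were higher in ferulate than in citrate (median log2 fold change 7.51). Of the 11 genes of the protocatechuate branch 10 were higher, 0 were lower and 1 were not called. In the tricarboxylic acid cycle, 0 were higher, 11 were lower and 10 were not called of 21, with icd at -1.77 ± 0.17. Serine against citrate gave 807 called genes, 403 higher and 404 lower in serine. In flagella and chemotaxis, 35 were higher, 0 were lower and 50 were not called of 85, with flgB at 2.31 ± 0.19, and in the tricarboxylic acid cycle 1 were higher, 14 were lower and 6 were not called of 21. Ferulate against serine gave 1108 called genes, 516 higher and 592 lower in ferulate. Of 54 ribosomal protein genes, 19 rose, 0 fell and 35 were not called in ferulate against serine, while in serine against citrate 2 were higher, 22 were lower and 30 were not called. The gene sda-3 was higher in serine than in citrate by 6.12 ± 0.19 (adjusted p = 8.1e-16) and lower in ferulate than in serine by -6.87 ± 0.21 (adjusted p = 6.0e-17) on the log2 scale. The lists were not tested by camera between these sources.

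Genes called in the same direction against each of the other 3 sources were counted as higher or lower in 1 source. Serine had the most such genes, 229 higher and 143 lower than in each other source. In ferulate, 143 were higher and 12 lower, in citrate 96 were higher and 29 lower, and in glucose 81 were higher and 214 lower. By the smallest of its 3 log2 fold changes, the serine genes were led by sda-3 at 6.12, PP_3176, of the major facilitator family, at 4.68, and aapJ, the binding protein of an amino acid ABC transporter, at 3.57. The ferulate genes were led by vanA at 8.14, PP_3355 at 7.93 and fcs at 7.61. The citrate genes were led by PP_1953 at 5.98, lctP at 5.45 and PP_0147 at 4.92, and the glucose genes by PP_1017 at 7.64, PP_1016 at 7.51 and PP_1015 at 6.76. The order depended on single libraries, and without 1 library other genes could replace 1 of the 3 in ferulate, glucose and serine. PP_3355 stood at 7.20 without glucose library 1 and PP_1016 at 7.90 without ferulate library 3, whereas sda-3 led the serine genes whichever library was left out. At 1617 ± 47.1 CPM in serine, aapJ was next highest in ferulate, at 136 CPM. If the 3 comparisons behind each count were independent, the expected numbers of higher genes were 10.4 in serine, 4.07 in ferulate, 5.34 in citrate and 2.1 in glucose. In 20 simulations without any effect, 0 genes were higher or lower in 1 source. As no gene was changed in them, they cannot show what shared libraries add where many genes differ. The 3 libraries of a source serve in all 3 of its comparisons and cannot be split into 2 sets of at least 2, so part of the excess over independent comparisons may come from shared libraries.

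**Figure D4:**
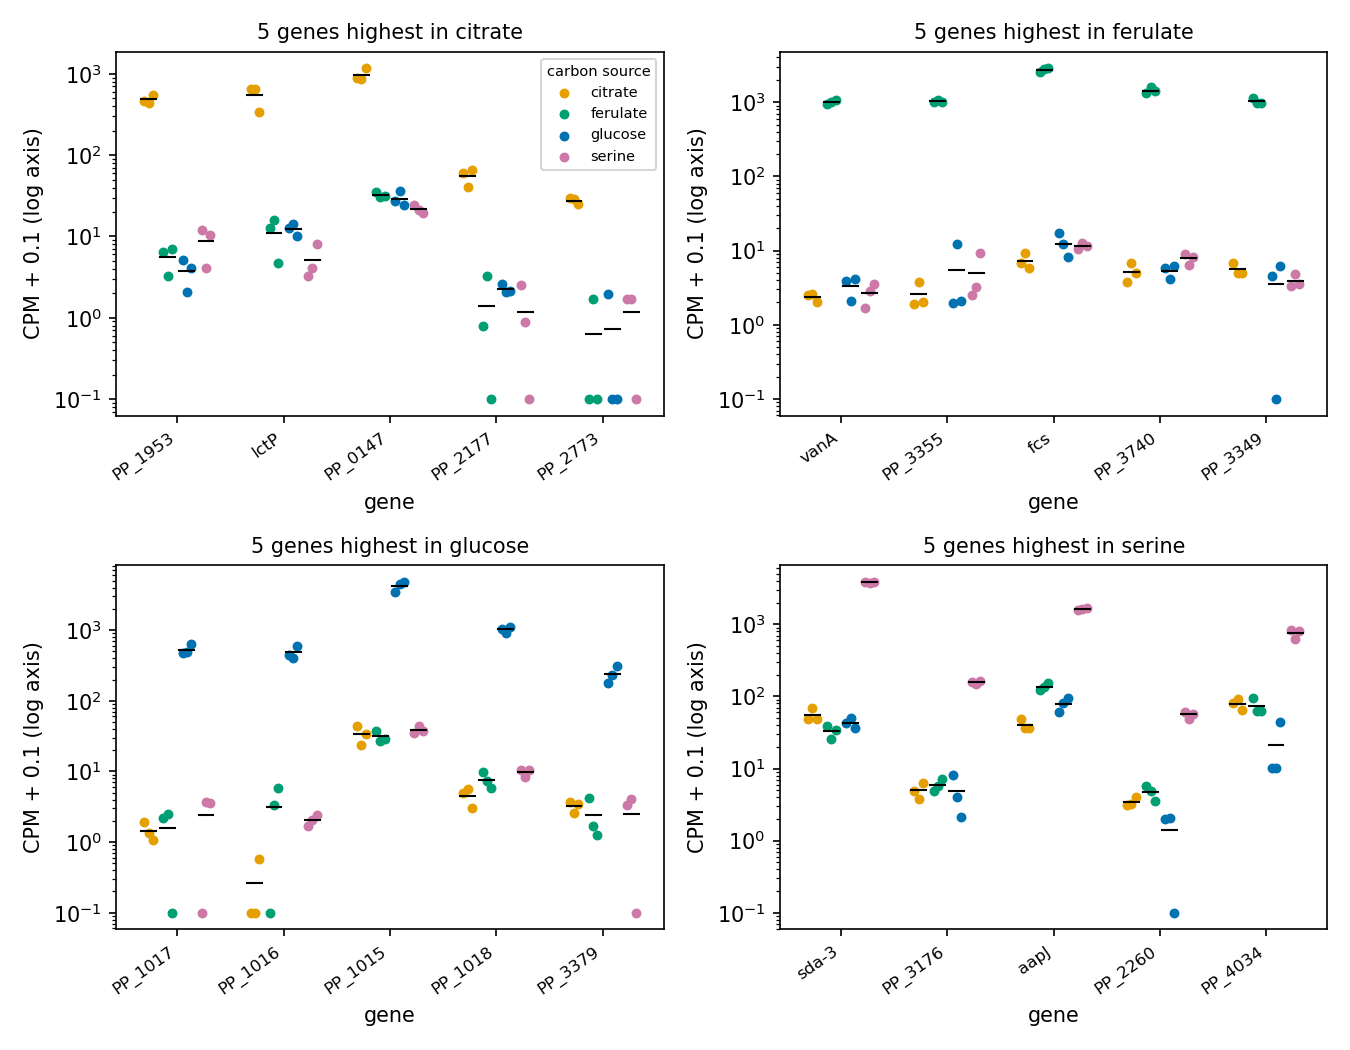
Each point is 1 library, as normalised CPM plus 0.1 on a log axis, for the 5 genes that lead each source, with black bars at the mean of the 3 libraries. In each panel the points of the named source lie above those of every other source, as for sda-3 at 3845 ± 48.7 CPM in serine (SD, n = 3) and at most 55.3 CPM on average elsewhere.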

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

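The 3 tests of antisense rRNA counts in this part were chosen only after the counts had been seen, and the wrong-strand test was narrowed to features opposite strong genes after a first form over all antisense features had been looked at.

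The 72 predicted RNAs were left out of the comparisons, and their levels differed between the sources. Tested with the library sizes of the genes by edgeR quasi-likelihood, 21 were higher in citrate, 17 in ferulate and 21 in serine, and 19, 5 and 16 were lower. With glucose library 1 as the only glucose library, a setting chosen after the data had been seen, 14, 7 and 15 of the higher and 11, 2 and 12 of the lower ones were still called. Of the 19 lower in citrate, 11 had a glucose SD of more than 0.5 of the mean and 10 lay opposite another feature, such as that at 5390022 to 5390388 on the minus strand, with 966, 70120 and 21949 CPM in glucose libraries 1, 2 and 3. Counts on the wrong strand in libraries 2 and 3 may be a cause, which was not tested for these RNAs. The RNA at positions 2388343 to 2388754 on the minus strand, between PP_2095 and PP_2096, rose in citrate by a log2 fold change of 3.79 ± 0.33 (adjusted p = 5.4e-09), from 3036 ± 633 to 42054 ± 4891 CPM on the scale of the genes (SD, n = 3). In serine the same RNA stood at 161222 ± 55856 CPM on the scale of the genes. The RNA at 3787214 to 3787239 on the minus strand, between PP_3349 and PP_3350, had 1912 counts in ferulate and 3 in glucose, a ratio of 466 with a 95% interval of 159 to 2262 (fitted log2 fold change 8.83 ± 0.36). All 3 glucose counts lay in glucose library 1. The ratio was 287 (98 to 1392) against that library alone, and without it the RNA was at least 188-fold higher in ferulate. This feature is shorter than the 100 bp reads, and both neighbours rose too. PP_3349 and PP_3350 stood at 979 to 1129 and 4573 to 6214 CPM in ferulate and at most at 6.03 and 20.7 CPM in glucose. Whether its counts are separate from those of its neighbours was not tested. The RNA at 4812496 to 4812580 on the plus strand, between PP_4238 and PP_4239, rose in serine by 6.48 ± 0.27 (adjusted p = 2.1e-14), from 4.72 ± 3.13 to 544 ± 37.7 CPM on the scale of the genes (SD, n = 3). It is also shorter than the reads.

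Counts antisense to rRNA were left out as well, and came to 8.75 and 4.05 per 100 rRNA counts in glucose libraries 2 and 3. Genomic DNA was argued against, because 99.9% or more of the genes held fewer counts per kb than the antisense rRNA features, 45805 and 23611 per kb against a median gene at 21.6 and 22.5. Reads counted on the wrong strand may be a cause, since the 7 antisense features opposite strong genes rose by medians of 103 and 42.1 times per host count over glucose library 1, with ranges of 18.2 to 169 and 11.2 to 76.3. The sum of all 10 antisense features of genes other than rRNA was divided by the gene counts of its library, not by host counts. It stood at 1.96 and 0.832 times its value in glucose library 1, where 3 features opposite weak genes held 98.3% of these antisense counts. Growth on glucose as a cause stays open, because glucose library 1, at 0.223, is the only other library of that source.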

How the results depend on the processing

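The settings with a mean of at least 30 CPM, counts rounded to the nearest, glucose library 1 alone and predicted RNAs kept were chosen only after the data had been seen. Without the fold threshold, adjusted p alone gave 2200, 1471, 2684, 1889, 1946 and 2320 genes in citrate, ferulate and serine against glucose, ferulate and serine against citrate and ferulate against serine, and 228, 435 and 623 genes higher in citrate, glucose and serine than in each other source. Genes lower than in each other source went from 29, 12, 214 and 143 to 155, 57, 412 and 451 in citrate, ferulate, glucose and serine. This setting calls smaller changes by its construction. Genes higher in citrate numbered 61 at a mean of at least 30 CPM, where fewer genes were tested (3219), and genes lower in citrate 19, as many as at an adjusted p of 0.01. Under the other settings run, the counts of called genes and of genes higher or lower in 1 source stayed within 1.5 times the reported ones. Leaving out 1 replicate gave 1017 to 1097, 587 to 662, 1622 to 1690, 732 to 881, 782 to 863 and 1091 to 1170 called genes in the same order. With glucose library 1 alone, 1100, 628 and 1612 genes were called against glucose, the lone library being assumed to vary like the others.

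The number of lists that passed moved more than the genes did. With a correlation preset at 0.01 it was 12, 19 and 11 in citrate, ferulate and serine against glucose, while fry, which asks whether a list changed at all and not whether it changed more than other genes, gave 22, 25 and 22. With glucose library 1 alone it was 2, 4 and 2, and at a mean of at least 30 CPM 1, 3 and 0. Leaving out 1 replicate gave 1 to 2, 2 to 4 and 0 to 2, with 0 in serine without glucose replicate 1 and 2 in citrate and in serine without glucose replicate 3. The cause was not tested.

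A replicate block was run although the replicate numbers did not pair the samples. Residuals of samples with the same number had r of -0.29 to 0.16 across genes (mean -0.01, 18 pairs), and those with different numbers -0.24 to 0.27 (36 pairs). With the block, 1066, 628 and 1637 genes were called against glucose, and 0, 1 and 0 lists passed. The cause was not tested.

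Of 6423 values of named genes under the alternatives, 6202 stayed on their side of the threshold, 146 lost and 75 gained the call, and 0 reversed. With glucose library 1 alone 433 of 469 stayed, and without 1 replicate 2671 of 2810. The alternatives planned for normalized values were not run, since counts were used. Depth limits the genes of low level most, since glucose libraries 2 and 3 held 570393 and 577327 gene counts.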

Other observations

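The tests of the share of higher genes and of the ribosomal protein genes, and the runs of genes with 1 library left out, were chosen only after the results had been seen. Several stretches of neighbouring genes on 1 strand were higher in 1 source than in each other source. In ferulate, PP_1565 to PP_1575, 11 genes with a phage portal protein, a capsid protein and a tail protein (positions 1758834 to 1765526, plus strand), had smallest log2 fold changes of 1.29 to 2.98. Their sum varied between cultures, at 757, 977 and 2920 CPM in ferulate libraries 1, 2 and 3. Without library 3, 6 of the 11 were still higher than in each other source (0.43 to 2.16), and with glucose library 1 alone 4 were. PP_0175 to PP_0180, 6 genes with a fusaric acid resistance protein and an RND efflux transporter (226725 to 233811, plus strand), had 1.24 to 3.72. Without glucose library 1, 5 of these 6 were still higher than in each other source, and the lowest value was 0.95. PP_2675 to PP_2681, 7 genes with a quinoprotein ethanol dehydrogenase and an aldehyde dehydrogenase (3063713 to 3071055, plus strand), had 2.37 to 5.31, and PP_2665 to PP_2669, which start with the regulator gene agmR, had 1.60 to 4.60.

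In serine, PP_0103 to PP_0111, 9 genes with the cytochrome c oxidase subunits (108809 to 117219, plus strand), had smallest log2 fold changes of 1.40 to 3.09. The amino acid transporter genes aapJ, aapQ, aapM and aapP (PP_1297 to PP_1300) had 2.29 to 3.57, PP_2260 to PP_2264, of a sugar ABC transporter, 1.76 to 3.52, and PP_4863 to PP_4867, of a branched-chain amino acid ABC transporter, 2.03 to 2.51. In glucose, PP_1010 to PP_1020 (1151274 to 1164546, plus strand) had 1.98 to 7.64, and PP_3781 to PP_3790, with a non-ribosomal peptide synthetase (4308593 to 4319834, plus strand), 1.17 to 3.75. In citrate, gcvT-1, sda-2, gcvP-1 and gcvH (PP_0986 to PP_0989) had 1.04 to 1.27, and PP_1415 to PP_1419, with the TctA, TctB and TctC genes, 1.90 to 3.36. In all there were 2 such runs of at least 4 genes in citrate, 8 in ferulate, 3 in glucose and 4 in serine, and the highest number in 10000 random placings of as many genes was 1. With 1 library left out or glucose library 1 alone there were 5 to 9 in ferulate, 3 in glucose and 4 to 5 in serine. In citrate there were 1 to 2, and in 4 of these 13 settings only 1, as many as the highest of the random placings. There PP_0986 to PP_0989 fell below 4 genes, whereas PP_1415 to PP_1419 kept all 5 genes in each setting. That genes of 1 transcription unit change together is a candidate explanation for ferulate, glucose and serine. In citrate it rests on PP_1415 to PP_1419, the run that held in each setting.

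Among genes called against glucose, 65.5%, 72% and 57% were higher in citrate, ferulate and serine. With an adjusted p alone the shares were 50%, 51.9% and 50.3%. A loss of low genes in the shallower glucose libraries 2 and 3 was argued against as the whole cause, because with glucose library 1 alone the shares were 62.9%, 70.4% and 54.8%, above 50% by more than the 2.89, 8.91 and 1.76 points over which they ranged when 1 replicate was left out. What else could account for the shares was not tested.

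Ribosomal protein genes had a median log2 fold change of -1.76 in serine against glucose, with 43 of 54 lower, but the list did not pass by camera (adjusted p = 0.169). Library scaling was argued against, because a library factor moves all genes alike, while the median of the list lay at -1.79 relative to that of all genes and its upper quartile at -1.08. The shallower glucose libraries 2 and 3 were argued against too, because the median was -1.70 with glucose library 1 alone. The density of the culture at harvest and the carbon source cannot be told apart, as only 1 harvest density or range was stated per source, so either may account for the difference.

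Other splits of the samples were counted for each result. For the 6 comparisons of 3 with 3 samples, 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, gave as many called genes in each. The real values were 1047, 632, 1633, 783, 807 and 1108 genes, and the highest other values 0, 1, 0, 0, 0 and 0. For the lists, the real values were 1, 3 and 1 and the highest other 0 (camera), again with 1 of 10 splits as high. Of 100 groupings of the 12 samples into 4 groups of 3, 3 had a largest group with as many higher genes as citrate (96), ferulate (143) or glucose (81), and 1 as many as serine (229), the real one included. The highest other value was 200, from a grouping that kept the 3 libraries of 1 source together, as 7 did, and the 92 that kept no source together gave at most 0. Groupings that mix sources place the differences between sources inside their groups, so they could hardly call genes. The counts show that libraries of a source resemble each other, and cannot exclude chance for these genes.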
